A study of Homo sapiens with 6 samples.

How the data were processed

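RNA of 3 parent and 3 IDTC colony samples of the WM164 melanoma line was measured on Affymetrix whole-transcript arrays. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit, converted with the Ambion WT Expression Kit, labelled with biotin using the Affymetrix WT Terminal Labeling Kit, and read in a single colour. Samples were assigned to groups from their titles. The design text says that the cells were kept in triplicate and each sample's RNA isolated on its own, without saying whether these were separate cultures, so p-values measure only the spread between these samples, which may be technical. No scan date or batch was given in the sources used here, and a batch that follows the groups cannot be told apart from them.

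The deposited values are log2 expression values of each probe set, as their range shows, and the submitters' processing notes name Affymetrix Expression Console. The version, background correction, summarisation and normalization of these log2 values are not given in the sources used here. Array medians lay between 6.25 and 6.34. Of 18417 genes tested, 30.4% had at least 2 identical values among the 6 arrays. Arrays have no read depth, and the number of arrays limits the precision.

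The table held 33297 probe sets. The platform annotation gave 1 gene symbol for 19460, several for 1754 and none for 12083. Of the probe sets with 1 symbol, 19429 matched the reference gene table (assembly GRCh38.p14) by Entrez ID and 0 symbols changed. That table was used only for names and for the order of genes. Probe sets without a single symbol stayed out of the main comparison. For the 769 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays was used, leaving 18417 genes with no filter on dim ones.

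Colonies were compared with parent cells by limma (lmFit and eBayes, 2-sided, group as the only term), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are colony minus parent on the log2 scale. For the 27 gene lists (20 of biology and 7 of other cell types and handling) limma's camera was used with a preset inter-gene correlation of 0.01, adjusted over the lists. Of 525 list memberships, 479 were measured. Camera compares a list with the other genes, whereas fry tests whether a list's genes move on balance in 1 direction. All 4 lists that camera called lost the call with an estimated correlation.

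The design, lists, alternatives and rule for named genes were fixed before the data were examined. The rule took the 8 largest rises and 8 deepest falls among genes past the test whose groups did not overlap, leaving out non-coding, uncharacterised, pseudogene and Y-linked symbols and XIST. It also took the 2 members of each biology list with the largest change past the test, up to 2 members of each control list past the test by at least 2-fold, and 12 genes whatever their values, namely MITF, SOX10, DUSP6, CCND1, BRAF, AXL, EGFR, PDGFRB, NGFR, KDM5B, ABCB5 and MKI67. Of the 69 genes it gave, 68 were measured. Other members named in the text were chosen after their values were seen.

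The alternatives were arrays shifted to a common median, quantile normalization, only genes above the median expression, the mean of a gene's probe sets, all probe sets, eBayes with trend and robust settings, the replicate number as a term, each array left out, an estimated correlation and fry. Subtracting the median of the 50 nearest expressed genes (25 on each side) was added after the data were seen, and was applied only to genes above the median expression, all others being left as they were. Also added then were 6 further gene lists: HIF targets outside glycolysis, further immediate early genes, cancer-testis antigens, Wnt regulators and targets, glial and Schwann cell genes, and replication-dependent histone genes. The scan along the gene order, also added then, took windows of 50 genes above the median expression, with 1000 shuffles of the gene order.

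Both procedures were tested on simulated data. With 200 changed genes among 18417, limma called 70% of those set at a log2 change of 0.5, 94% at 1 and 100% at 2 and at 3, with 7 calls among 18217 unchanged genes. The simulated noise was independent between genes and far fewer genes changed than were called in the data, so these rates need not hold there. The scan found a planted block of 120 genes shifted by 0.5 and no other. That shift exceeds the median of every block found in the data, the largest being 0.417. Weaker or shorter blocks were not simulated. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.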

Results

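Gene expression was measured in WM164, a melanoma cell line with a mutant BRAF kinase. Parent cells, which per the series title received the solvent DMSO, were set against colonies kept for 60 days in 500 nM PLX4032, a small-molecule inhibitor of mutant BRAF also known as vemurafenib. The labels call the treated samples IDTC colonies and describe them as resistant. Each group had 3 samples, each on its own 1-colour Affymetrix whole-transcript array, and the comparison asks how expression in the colonies differed from that in the parent cells. The number of arrays limits the precision of every value. Arrays of the same group correlated at 0.997 to 0.998 across genes, and arrays of different groups at 0.967 to 0.969.

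Colonies differed from parent cells at a large share of the genes, most of them by a small amount. Of 18417 genes tested, 3849 were higher and 4212 lower in the colonies (limma, adjusted p under 0.05), and 488 of the higher and 508 of the lower genes differed by at least 2-fold. Among hypoxia and glycolysis genes 15 of 18 fell, and camera placed the list below other genes (adjusted p = 3.8e-07, and adjusted p = 0.365 with an estimated correlation). In 3 further lists that passed camera, 11 of 22 interferon-stimulated, 7 of 10 antigen presentation and 12 of 19 lysosome and autophagy genes rose. None of these 3 passed with an estimated correlation (adjusted p = 0.365, adjusted p = 0.426 and adjusted p = 0.517). MITF, the lineage transcription factor of melanocytes, showed a log2 difference of 0.00 ± 0.05 that did not pass the test. A change under 1.5-fold accounted for 5205 of the 8061 calls, against a median SD within groups of 0.08 on the log2 scale.

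The largest measured rise was that of GRIK3 (probe set 7914974), a subunit of kainate-type glutamate receptors, from 6.10 ± 0.10 to 10.72 ± 0.02 on the log2 scale (mean ± SD, n = 3 arrays per group). LPAR1, a receptor for lysophosphatidic acid, rose by 4.21 ± 0.08 (log2 fold change ± SE). The actin-associated protein gene PDLIM1 rose by 4.03 ± 0.10 and the secreted Wnt antagonist gene DKK1 by 4.01 ± 0.14. PDGFD, which encodes a ligand of the PDGF receptor beta, rose by 3.90 ± 0.07. Next came the transcription factor gene TOX (3.63 ± 0.08), the secreted protein gene NELL1 (3.59 ± 0.06) and BCAN, which encodes the proteoglycan brevican (3.58 ± 0.04). The 8 adjusted p-values ranged from 2.7e-08 for BCAN to 8.4e-07 for DKK1. The 50 expressed neighbours in the gene order had a median of 0.29 for BCAN and -0.16 for TOX.

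The deepest measured fall was that of IGFBP5 (probe set 8058857), a binding protein of insulin-like growth factors, from 10.92 ± 0.02 to 6.15 ± 0.09. CD96, an immunoglobulin-family receptor, changed by -4.63 ± 0.05 and GMPR, a guanosine monophosphate reductase, by -4.54 ± 0.09. PNMA5 changed by -4.45 ± 0.14, and PRKAA2, a catalytic subunit of the energy sensor AMPK, by -4.08 ± 0.09. The calcium channel subunit gene CACNA2D1 (-3.92 ± 0.05), the gene TMEM163 (-3.90 ± 0.08) and LPXN, which encodes the focal adhesion protein leupaxin (-3.88 ± 0.06), followed. Their adjusted p-values lay between 2.7e-08 for IGFBP5 and 5.3e-07 for PNMA5. GMPR fell beside a neighbour median of 0.26. For 7 of the 8 rises and 7 of the 8 falls, the exceptions being BCAN and LPXN, the lower group's mean lay below the lowest array median (6.25), and whether it lay above background was not tested, so these differences and their order are those of the deposited values. The same held for IFIT1, IFIT2, IFI27, CTSK, BCL2A1, LRRTM4, AXL, EGFR, PDGFRB, FAS, BMF, ALDH1A1, ABCB5, CCL2, CXCL8, FBN1, LYZ and FCER1G in their lists. GMPR had identical deposited values on all 3 parent arrays, as had 215 genes in all, and 471 genes had identical values on all 3 colony arrays, so an SD of 0 is a property of the deposited values.

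Hypoxia and glycolysis genes had the smallest camera p of the 27 lists (adjusted p = 3.8e-07, and adjusted p = 0.365 with an estimated correlation). Of 18 measured members, 15 fell, none rose and 3 did not pass the test, with the same counts adjusted over the list alone. SLC2A1 (probe set 7915472), the main glucose transporter of many cell types, changed from 12.18 ± 0.01 to 9.76 ± 0.07, and NDRG1, a stress-responsive gene induced by low oxygen, by -2.27 ± 0.05. The glycolytic kinase genes HK2 (-1.90) and PFKFB4 (-1.87) fell as well, while HK1 (-0.02), EGLN3 (0.05) and ALDOC (0.10) did not pass the test. The list's median was -0.73.

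**Figure D1:**
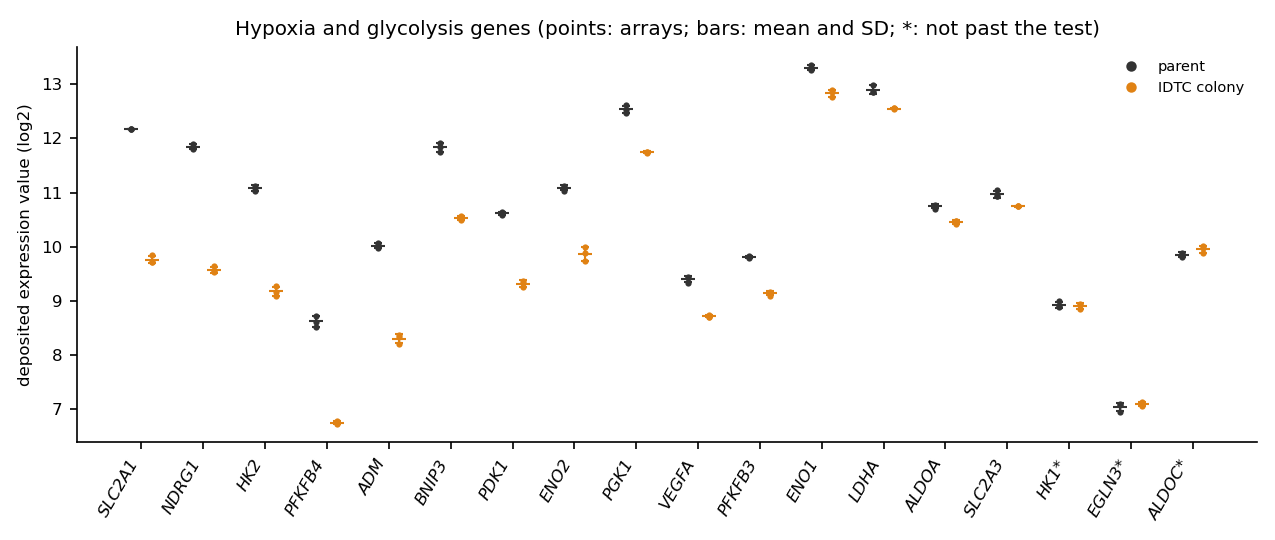
Deposited log2 expression values of the 18 measured hypoxia and glycolysis genes, ordered by log2 fold change, with points for the 3 parent and 3 IDTC colony arrays and bars for mean and SD. The 15 genes without an asterisk were lower in the colonies, from SLC2A1 (-2.41) to SLC2A3 (-0.22), and the 3 with one did not pass the test.

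Interferon-stimulated genes rose in 11 of 22 measured members, fell in 1 and did not pass the test in 10, both over all genes and adjusted over the list alone. The antiviral RNA-binding protein genes IFIT1 (2.57 ± 0.10) and IFIT2 (1.84 ± 0.19) had the largest measured rises, from parent means of 4.87 and 4.81 not shown to be above background, and ISG20 (-0.21) fell. ISG15 (-0.01) and IFI27 (-0.05) did not pass the test. The list was higher than other genes by camera (adjusted p = 0.0114), with adjusted p = 0.365 with an estimated correlation. With only genes above the median expression, which kept 6 of the 22 members, it did not pass (adjusted p = 0.19).

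Antigen presentation genes rose in 7 of 10 measured members, fell in 1 and did not pass the test in 2, again with the same counts adjusted over the list alone. TAPBP, which helps load peptides onto class I molecules, rose by 1.08 ± 0.05 and B2M, their shared light chain, by 0.77 ± 0.11. The classical class I heavy chain genes were not analysed here. The list passed camera narrowly (adjusted p = 0.047), with adjusted p = 0.426 with an estimated correlation. It did not pass without parent replicate 1 (adjusted p = 0.0581), without parent replicate 2 (0.0532), without parent replicate 3 (0.0629), after quantile normalization (0.0521), with the mean of a gene's probe sets (0.0582), with only genes above the median expression (0.345) or, in an alternative chosen after seeing the data, with the neighbourhood median subtracted (0.0785), which changed only the 5 of its 10 members above the median expression.

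Lysosome and autophagy genes rose in 12 of 19 measured members, fell in 3 and did not pass the test in 4, counts that held when adjusted over the list alone. CTSK, a cysteine protease of the lysosome, rose by 2.46 ± 0.09, and HEXA, a subunit of the lysosomal enzyme hexosaminidase A, by 1.08 ± 0.05. The membrane protein gene LAMP2 (1.01) rose too, while SQSTM1 (-0.30), an autophagy cargo receptor gene, fell. Camera placed the list above other genes (adjusted p = 0.0229), with adjusted p = 0.517 with an estimated correlation. With only genes above the median expression, which kept 17 of the 19 members, it did not pass (adjusted p = 0.226).

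**Figure D2:**
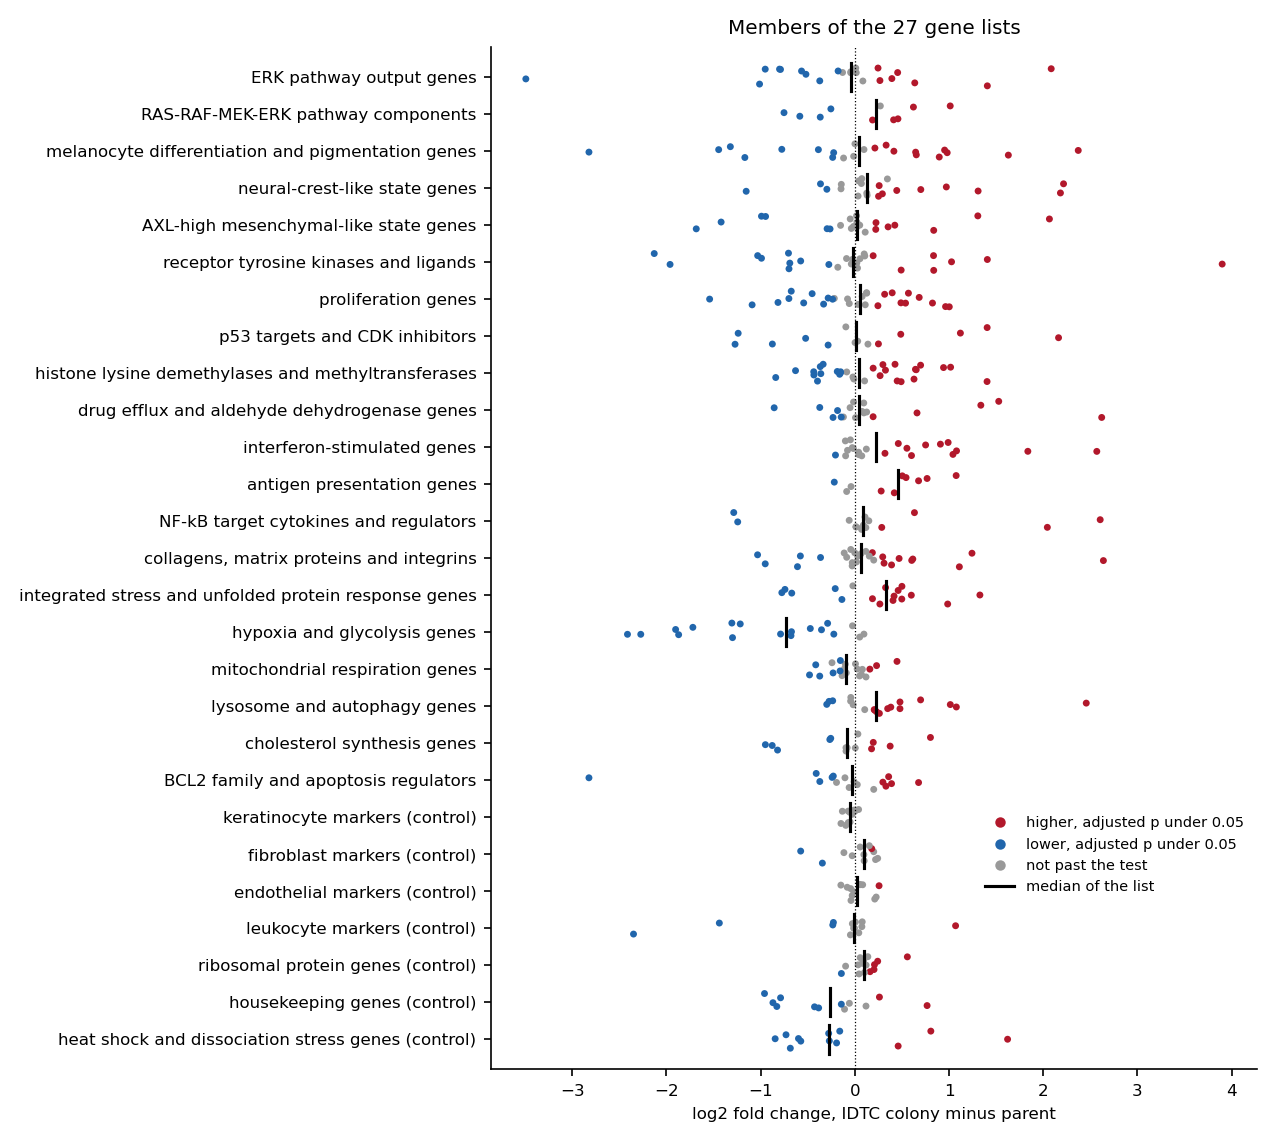
Log2 fold change (IDTC colony minus parent) of each measured member of the 27 gene lists, with a bar at each list's median and colour for members that passed limma's test as higher or lower. The hypoxia and glycolysis genes lie to the left with a median of -0.73, and the keratinocyte markers hold no coloured point.

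ERK pathway output genes, which are transcribed in response to the kinase cascade below BRAF, went both ways. Of 22 measured members, 7 rose, 9 fell and 6 did not pass the test, with the same counts adjusted over the list alone. The list did not pass camera (adjusted p = 0.627, and adjusted p = 0.854 with an estimated correlation). Fry, which tests another question and called 17 of the lists, gave it as lower on balance (adjusted p = 2.0e-05). LIF, a cytokine gene, changed by -3.49 ± 0.04, whereas FOS, an immediate early transcription factor gene, rose by 2.09 ± 0.08. DUSP6, a phosphatase that acts on ERK, changed by -0.79 ± 0.04 beside a median of -0.36 among its 50 expressed neighbours in the gene order. The cyclin gene CCND1 changed by -0.18 ± 0.04 (adjusted p = 0.011), a call that ended after quantile normalization (-0.08, adjusted p = 0.21). Among RAS-RAF-MEK-ERK pathway components, 5 of 10 measured genes rose, 4 fell and 1 did not pass the test (6 and 4 adjusted over the list alone). The scaffold gene KSR1 rose by 1.01 ± 0.11 and the MEK gene MAP2K1 changed by -0.75 ± 0.05, and the list did not pass (adjusted p = 0.657). BRAF itself was not analysed here.

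Melanocyte differentiation and pigmentation genes split almost evenly, with 10 of 22 measured members higher, 8 lower and 4 not past the test, the same adjusted over the list alone. EDNRB, the endothelin receptor of the melanocyte lineage, rose by 2.37 ± 0.07 beside a neighbour median of 0.10, and BCL2A1, an anti-apoptotic gene, changed by -2.82 ± 0.07. MITF (probe set 8080938) was at 11.14 ± 0.01 in parent cells and 11.14 ± 0.06 in colonies (log2 fold change 0.00 ± 0.05, adjusted p = 0.986), while its 50 expressed neighbours had a median of -1.05. SOX10, a transcription factor of the neural crest lineage, rose by 0.42 ± 0.06. The list did not pass camera (adjusted p = 0.638).

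Neural-crest-like state genes included 9 that rose, 3 that fell and 9 not past the test among 21 measured, the same adjusted over the list alone. The synaptic membrane protein genes LRRTM4 (2.22 ± 0.11) and SLITRK6 (2.18 ± 0.07) had the largest measured rises, SLITRK6 beside a neighbour median of 0.15. NGFR, the nerve growth factor receptor that marks this state in melanoma, rose by 0.97 ± 0.07 beside a neighbour median of 0.35. The list missed camera's threshold (adjusted p = 0.0855) and passed it over all probe sets (adjusted p = 0.0462). In that setting each member still entered with the same 1 probe set, and only the probe sets it was compared with increased. An estimated correlation, not run in that setting, gave adjusted p = 0.426 in the main comparison.

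In the AXL-high mesenchymal-like list, 7 of 22 measured genes rose, 6 fell and 9 did not pass the test, also adjusted over the list alone. The transcription factor gene JUN rose by 2.07 ± 0.05, the matrix glycoprotein gene TNC changed by -1.68 ± 0.05 and the receptor gene AXL rose by 0.84 ± 0.10. Its median (0.02) and its mean (-0.01) differed in sign, and it did not pass (adjusted p = 0.801). Among 26 receptor tyrosine kinases and ligands, 7 rose, 9 fell and 10 did not pass the test (7 and 10 adjusted over the list alone). FGFR1, a receptor for fibroblast growth factors, changed by -2.13 ± 0.04 and EGFR, the epidermal growth factor receptor, by -0.99 ± 0.10. PDGFRB, the receptor for PDGFD, was at 5.79 ± 0.15 and 5.77 ± 0.14 (log2 fold change -0.01 ± 0.10, adjusted p = 0.927), and the list did not pass (adjusted p = 0.766).

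Proliferation genes were divided, with 10 of 28 higher, 10 lower and 8 not past the test, the same adjusted over the list alone. CCNE2, a cyclin of the G1 to S transition, changed by -1.54 ± 0.10 (neighbour median -0.06) and RRM2, a subunit of ribonucleotide reductase, by -1.09 ± 0.05, while the proliferation marker MKI67 rose by 0.57 ± 0.05 beside a neighbour median of 0.24. The list's median (0.06) and mean (-0.02) had opposite signs (camera adjusted p = 0.811). Among p53 targets and CDK inhibitors, 5 of 14 rose, 5 fell and 4 did not pass the test, also adjusted over the list alone (adjusted p = 0.801). The death receptor gene FAS (2.16 ± 0.15) and the RNA-binding protein gene ZMAT3 (1.41 ± 0.07) had the largest measured rises, and CDKN1A, the CDK inhibitor p21, fell (-1.24). In the BCL2 family and apoptosis list, 5 of 16 rose, 5 fell and 6 did not pass the test (6 and 5 adjusted over the list alone, camera adjusted p = 0.971), and the pro-apoptotic gene BMF rose by 0.68 ± 0.08.

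Histone lysine demethylases and methyltransferases changed in 26 of 30 genes, 14 of them higher and 12 lower, the same adjusted over the list alone. The list did not pass camera (adjusted p = 0.627). Of the 30 genes, 29 lay above the median expression, where calls were common. With only such genes tested 6735 were called, against 8061 of all 18417. SETDB2, a histone H3 lysine methyltransferase, rose by 1.40 ± 0.07 and the demethylase gene KDM1B by 1.02 ± 0.05, beside neighbour medians of 0.28 and 0.18. KDM5B, a demethylase linked to slow-cycling melanoma cells, rose by 0.65 ± 0.05 beside a neighbour median of 0.22. Of 18 drug efflux and aldehyde dehydrogenase genes, 5 rose, 5 fell and 8 did not pass the test, also adjusted over the list alone (camera adjusted p = 0.627). The retinaldehyde-oxidising enzyme genes ALDH1A3 (2.62 ± 0.10) and ALDH1A1 (1.53 ± 0.08) had the largest measured rises, and the transporter gene ABCB5 did not pass (0.13 ± 0.06, adjusted p = 0.134).

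Integrated stress and unfolded protein response genes rose in 11 of 17 members, fell in 5 and did not pass the test in 1, the same adjusted over the list alone (camera adjusted p = 0.105). DDIT3, the stress-induced transcription factor CHOP, rose by 1.33 ± 0.06 and SESN2, a leucine sensor, by 0.99 ± 0.08. Among 15 NF-kB target cytokines and regulators, 4 rose, 2 fell and 9 did not pass the test, also adjusted over the list alone (adjusted p = 0.313). The chemokine genes CCL2 (2.60 ± 0.12) and CXCL8 (2.04 ± 0.09) had the largest measured rises, CXCL8 beside a neighbour median of -0.32. Collagens, matrix proteins and integrins included 10 higher, 5 lower and 12 not past the test of 27, the same adjusted over the list alone (adjusted p = 0.309). The gelatinase gene MMP2 rose by 2.64 ± 0.04 and the fibrillin gene FBN1 by 1.24 ± 0.08.

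Mitochondrial respiration genes moved little, with 3 of 20 higher, 6 lower and 11 not past the test, the same adjusted over the list alone (camera adjusted p = 0.638). IDH3A, a subunit of the citric acid cycle enzyme isocitrate dehydrogenase, changed by -0.48 ± 0.04, and the complex III subunit gene UQCRC2 rose by 0.45 ± 0.06. Cholesterol synthesis genes rose in 4 of 14, fell in 5 and did not pass the test in 5, also adjusted over the list alone (adjusted p = 0.627). The sterol carrier gene STARD4 changed by -0.95 ± 0.07 beside a neighbour median of -0.22, and the last-step enzyme gene DHCR7 by -0.88 ± 0.05.

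Markers of other cell types and of handling were read beside these lists. None of 11 keratinocyte markers passed the test by limma, over all genes or adjusted over the list alone. Among 12 fibroblast markers 1 rose and 2 fell (0 and 2 adjusted over the list alone), and among 12 endothelial markers 1 rose and none fell (0 and 0). Of 13 leukocyte markers, 1 rose and 4 fell, also adjusted over the list alone, with LYZ, the lysozyme gene, at -2.35 ± 0.10 and FCER1G, an immune receptor chain gene, at -1.44 ± 0.11. Ribosomal protein genes rose in 5 of 16 and fell in 1, and housekeeping genes rose in 2 of 12 and fell in 7 (2 and 8 adjusted over the list alone). Housekeeping genes shared PGK1 (-0.79) with the hypoxia and glycolysis list. They also shared B2M (0.77) with the antigen presentation list and SDHA with the mitochondrial respiration list. All 12 heat shock and dissociation stress genes passed the test, 3 of them higher and 9 lower. The 3 higher were FOSB, JUNB (0.81) and ATF3 (0.46), and the 9 lower ran from HSPE1 (-0.85) to HSPB1 (-0.16). FOSB, an immediate early gene that responds to cell handling, rose by 1.62 ± 0.19 alongside FOS and JUN. Camera's adjusted p was 0.0855 for housekeeping genes, 0.105 for heat shock and ribosomal genes, 0.638 for leukocyte, 0.657 for keratinocyte and 0.708 for fibroblast and endothelial markers. Over all probe sets, housekeeping genes (adjusted p = 0.0242) and heat shock genes (adjusted p = 0.0441) passed as lower. In that setting each member still entered with the same 1 probe set, and only the probe sets it was compared with increased. An estimated correlation, not run in that setting, gave both lists adjusted p = 0.74 in the main comparison.

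Differences also followed the order of genes along chromosomes, which was examined after the values had been seen. In windows of 50 neighbouring expressed genes, 20 blocks passed the limit set by shuffled gene order (a window median of 0.326), 8 of them higher and 12 lower in the colonies. They held 1931 of 9200 placed genes. The strongest higher block ran from NT5C3B to FOXK2 on chromosome 17, where 320 genes had a median of 0.42 and 83.8% had a log2 fold change above 0, whether or not they passed the test. The window median of largest size, 1.10 below the median of all expressed genes, lay on chromosome 3.

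**Figure D3:**
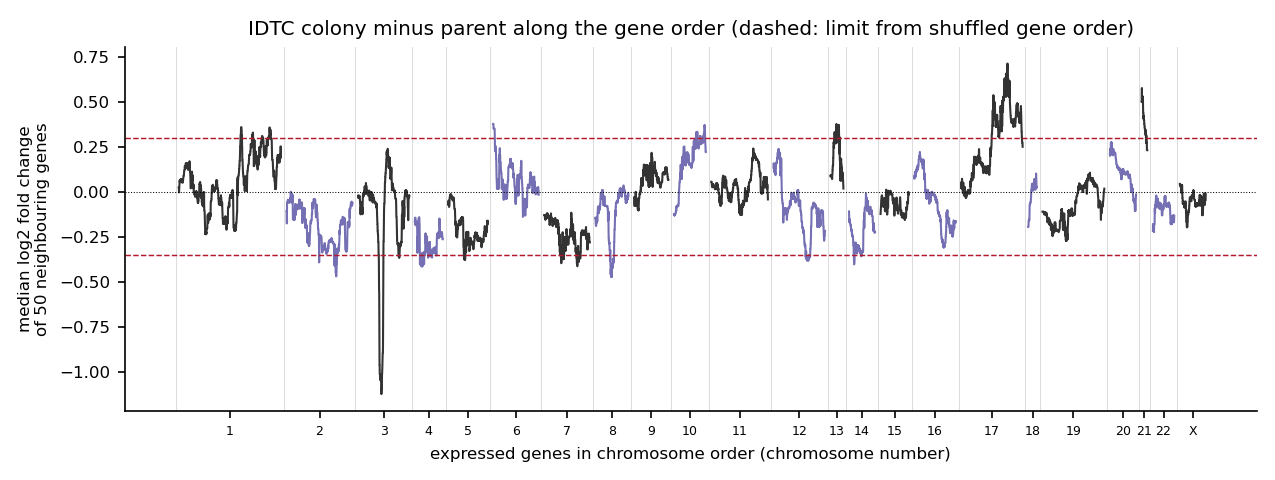
Median log2 fold change (IDTC colony minus parent) of 50 neighbouring expressed genes along chromosomes 1 to 22 and X, with dashed lines at the limit of 0.326 from shuffled gene order on either side of the median of all expressed genes. Chromosome 3 holds the deepest trough, and the second part of chromosome 17 and chromosome 21 lie above the limit.

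The trough on chromosome 3 spanned CFAP20DC to EPHA3, edges set after the values had been seen. Of its 36 expressed genes, 33 fell, 26 of them by at least 2-fold, with a median of -1.65, a 3.13-fold difference. PTPRG, a receptor tyrosine phosphatase gene, changed by -2.81, the glycogen branching enzyme gene GBE1 by -2.83 and CEP15 by -3.28. FHIT rose by 1.10, and MITF (0.00) and GPR27 (-0.01) did not pass the test. The 20 expressed genes before the segment had a median of -0.12 and the 20 after it 0.12. The colony arrays gave medians of -1.64, -1.72 and -1.62 for the segment against the parent mean.

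**Figure D4:**
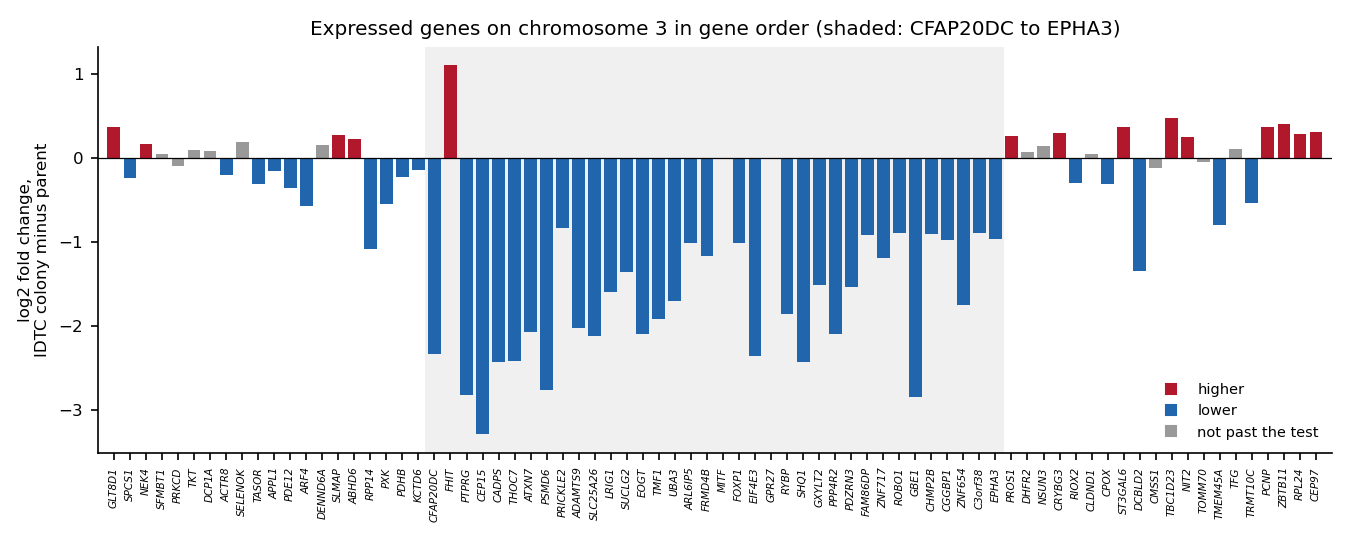
Log2 fold change (IDTC colony minus parent) of single expressed genes in gene order on chromosome 3, with the 36 genes from CFAP20DC to EPHA3 shaded and 20 genes on each side. Bars are coloured by limma's test, and within the shaded segment 33 genes were lower, FHIT was higher, and MITF and GPR27 did not pass.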

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

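The count of other splits was planned before the data were seen. Among 13837 probe sets with no gene name or several, which the comparison did not use, 123 were at least 2-fold higher and 106 at least 2-fold lower in the colonies, a signal outside the main measurement. Each was past an adjusted p of 0.05 by limma.

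The 6 arrays can be split into 3 and 3 in 10 ways, so a share of splits cannot go below 10%. In 1 of the 10 splits, the real one, 8061 genes were called, 996 of them at least 2-fold, and the highest count among the others was 0 for both. The real split called 4 gene lists and the highest of the others 2. These splits are too few for a share under 0.05. Every other split also mixes parent and colony arrays, so the group difference widens the spread within each side. Their low counts are therefore no measure of false calls.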

How the results depend on the processing

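Calls over all genes stayed within 1.5 times the main counts under the alternatives run, and no named gene or list that was called changed direction. Among named genes, CCND1 lost its call after quantile normalization (-0.08), and MITF gained one (1.05) only when the median of its neighbours was subtracted, an alternative chosen after seeing the data that adds the size of that median by construction. The number of gene lists called, 4 in the main comparison, was 1 with only genes above the median expression, 7 over all probe sets, 0 by camera with an estimated correlation and 17 by fry, which tests another question. The cause was not tested, except that fewer genes were tested under the first. Over all probe sets each list member still entered with 1 probe set, and only the probe sets compared with the lists increased. Hypoxia and glycolysis genes passed in all these alternatives but the estimated correlation. Leaving out each array in turn gave 3384 to 3860 higher and 3733 to 4494 lower genes, and 3 or 4 lists, antigen presentation being the list lost without any 1 parent array. Titles number both groups 1 to 3, but same-numbered arrays did not deviate together (correlations -0.0886, -0.0587 and -0.00962). With the replicate block, 3633 genes were higher and 3931 lower, 7424 of them shared with the main calls, and antigen presentation (adjusted p = 0.0537) was the 1 list lost. Shifting arrays to a common median moved the median of all genes from -0.00 to -0.03. Genes near background can show little change on these arrays.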

Other observations

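The hypoxia and glycolysis list and the ERK output list were fixed before the data were examined. The other gene lists and the scan along the gene order in this part were chosen after the main results had been seen. So was the test of a wrong label on a single array. The bounds of the other tests were set before their results. Cancer-testis antigens, normally limited to germ cells and some tumours, fell in 8 of 25 measured genes and rose in none, with SAGE1 (-3.17), SSX1 (-2.90) and MAGEA4 (-2.60) among the deepest (camera adjusted p = 0.0268, and adjusted p = 0.247 with an estimated correlation). Glial and Schwann cell genes rose in 9 of 17 and fell in 4 (adjusted p = 0.00843, and adjusted p = 0.246 with an estimated correlation). Its largest rises were GRIK3 (4.62) and BCAN (3.58), both already among the 8 largest rises above. The myelin protein gene MBP (2.31), the potassium channel gene KCNJ10 (2.47) and the axon-glia junction gene CNTNAP1 (2.87) rose, while SCRG1 (-3.40) and CDH19 (-1.91) fell. CNTNAP1 lay in the higher block on chromosome 17. GFAP (0.04), SOX8 (0.20), CNP (0.10) and NCAN (0.05) did not pass the test. Both lists were drawn up with some or all of their values in view, so neither count is independent evidence.

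Wnt regulators and targets rose in 7 of 23 and fell in 3 (adjusted p = 0.249). The repressor gene TCF7L1 (3.46) and the Wnt receptor ligase gene RNF43 (1.76) rose with DKK1, while LEF1 (-1.57), a transcription factor of the pathway, fell and AXIN2 (0.07), a common target, did not pass the test. Replication-dependent histone genes rose in 26 of 57 and fell in 13 (adjusted p = 0.0268, and adjusted p = 0.351 with an estimated correlation), from H2BC3 (-3.52) to H2BC21 (2.57). No neighbour median was subtracted for this list, and H4C2 was the last gene of a higher block on chromosome 6. A shared regional shift was therefore not separated from these counts. The genes H4C14 and H4C15 had the same values but were counted separately. In SAGE1, SSX1, MAGEA4, SCRG1, H2BC3, CNTNAP1, DKK1, AXIN2 and INSIG2 the lower group's mean lay below the lowest array median, and whether it lay above background was not tested.

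Neighbouring genes shifted together, most on chromosome 3. Variation of single arrays along the genome is argued against for chromosome 3. The largest window median of an array against the others of its group was 0.11, and that between groups, on chromosome 3, was 1.098. The other blocks passed a limit of 0.326, nearer to 0.11. In each of them all 3 colony arrays lay on the block's side of the parent mean. No parent array's block median differed from the other parents by more than 0.107. That was in the chromosome 13 block, where the colony arrays gave 0.287, 0.295 and 0.296. A shift made by 1 array is argued against in these blocks too, though they were found on the same arrays. A bound set beforehand against probe or GC composition was met by the dimmest genes of the blocks. Their median was 0.022 in the blocks' direction (upper 95% bound 0.028), against 0.337 for expressed genes. Genes near background can show little shift whatever the reason, but the 13 dimmest genes of the chromosome 3 segment had a median of -0.367. How much shift dim genes of the other blocks could show was not tested, so that bound was ill chosen and composition stays open. A copy number difference is a candidate explanation that also stays open. Of genes left out of the search, 75.8% lay on their block's side of the median of expressed genes, between the bounds of 60% and 80%. In the chromosome 3 segment, 6 genes below the median expression but brighter than those 13 had a median of -0.489, just short of -0.5. They were not used to find the segment. A wrong label on a single array is argued against by the lowest correlation within a group, 0.997, against the highest between groups, 0.969, while shared regulation, a different mix of cells and a wrong label for a whole group were not tested, and no DNA was analysed here.

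Hypoxia and glycolysis genes fell in 15 of 18 members (adjusted p = 0.365 with an estimated correlation). An intensity-dependent trend is argued against, since 0 of 10000 random lists matched on mean expression had a median as low as -0.733, the lowest being -0.607. A shift of the regions that hold the genes is argued against by a median of -0.767 after subtraction of each gene's neighbours. A lower activity of the hypoxia-inducible factor may take part, since 15 further targets outside glycolysis had a median of -0.441 (camera adjusted p = 0.0211, and adjusted p = 0.246 with an estimated correlation), with 9 lower, such as INSIG2 (-2.12) and P4HA2 (-1.27), and 3 higher, CITED2 (1.11), MXI1 (0.63) and JMJD6 (0.16). Whether culture density or medium on the day of harvest took part was not tested.

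Immediate early genes FOS, JUN and FOSB rose while the ERK feedback genes DUSP6, SPRY1 (-1.01) and SPRY4 (-0.80) fell. These feedback genes lay among falling neighbours, with medians of -0.36 for DUSP6, -0.30 for SPRY1 and -0.24 for SPRY4. With those medians subtracted the changes were -0.43, -0.71 and -0.55. DUSP6 was named beforehand, but SPRY1, SPRY4 and the grouping of these feedback genes were chosen after their values were seen. Among others of the kind, DUSP5 (-0.52, neighbour median 0.27) fell and SPRY2 (0.45, neighbour median 0.15) rose. DUSP4 (0.01), SPRED1 (-0.04) and SPRED2 (-0.04) did not pass the test. Of the 22 ERK output genes 7 rose, among them EPHA2 (1.41) and EGR1 (0.64), and 9 fell, and a general fall of ERK output stays open. A response to handling or medium change could not be decided. The median of 15 further immediate early genes, -0.0589, met a bound set beforehand against it, but 7 of them rose (ZFP36 0.86, IER2 0.63) and 4 fell (EGR3 -1.03, CSRNP1 -0.71), so a median near 0 says little.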
